A study of Homo sapiens with 40 samples.

How the data were processed

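CD3+ lymphocytes were sorted from tumor, adjacent normal tissue, lymph node and adrenal tumor of 3 patients who had lung cancer and received an antibody against PD-1, and were profiled with 10x Genomics 5' single-cell RNA sequencing. The deposited files hold 32 such libraries. They comprise 24 tumor libraries from 8 regions in each patient, 3 of adjacent normal tissue, 2 of lymph node from patients 1 and 2, and 3 of adrenal tumor from patient 1. A further 16 region files hold CD8 T cells of patient 1 that were sorted with peptide-HLA multimers, which bind T cell receptors of a given specificity. These were 8 files from tumor, 4 from lymph node and 4 from adrenal tumor. They were assigned to their tissue by the region names in the titles and were kept apart from the CD3-sorted libraries, since the kit and the software version differ.

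Per the file headers and the labels, the authors made each matrix with Cell Ranger, version 3.1.0 for the CD3-sorted and 7.0.0 for the multimer-sorted cells. The deposited values are raw counts, that is, whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization and with barcodes already called as cells. Every CD3-sorted matrix lists 33538 features. The submitters' notes name the genome build hg19 and give no annotation, so no coordinates are reported and genes are named by the symbols in the files. The multimer-sorted matrices also hold 12 barcode features of the multimers. These were left out of all gene expression analysis and enter only as sums.

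Cells were kept with at least 300 detected genes and at most 10% mitochondrial UMIs. This left 192018 of 217101 barcodes in the CD3-sorted libraries, 2606 to 11997 per library. Total UMIs per library ranged from 10845951 to 34631369, and the median UMIs per cell from 1071 to 3673. The CD8 gate took cells with a UMI of CD8A or CD8B, none of CD4 and at least 1 of CD3D, CD3E or CD3G, and the CD4 gate the reverse. Cells in clusters named as B, plasma, myeloid, epithelial, mast or stromal cells were removed from both gates. The gates held 658 to 5765 CD8 cells and 544 to 2134 CD4 cells per library, with at least 1879519 and 1247169 UMIs. Shares of cells carry Wilson 95% confidence intervals, which cover counting error only. XIST, Y-linked genes, T cell receptor and immunoglobulin variable segments and polymorphic HLA and KIR genes were neither tested nor named.

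Clusters were made with igraph 0.11.9 and leidenalg 0.10.2 in Python 3.11.15. A subsample of 1500 cells per library gave 2000 variable genes, 30 principal components of expression centred per patient, 15 nearest neighbours and Leiden clusters at resolution 1.0. All other cells took the majority cluster of their nearest cells. Tumor regions 7 and 8 of patient 1, which differed from regions 1 to 6 at many genes, were centred on their own mean, and genes that set them apart in both gates were left out of the variable genes, a choice made after the libraries had been seen. A cluster took a class name with the ending "-like" from marker lists fixed before the data were examined. The number of markers required for a name was set after the clusters had been seen. A patient's tumor share is the mean over its regions, and tumor was compared with normal by a two-sided exact sign-flip permutation test.

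For gene expression, counts of gated cells were summed per patient and tissue, giving 8 profiles per gate for tumor, normal and lymph node together. They were fitted with edgeR 4.0.16 (TMM normalization, filterByExpr with a minimum count of 10, quasi-likelihood F test) with the patient as a block, in R 4.3.3. The residual degrees of freedom were 3. The difference between the CD8 and CD4 responses was tested as an interaction over 12 profiles with patient by gate as a block. Adrenal tumor was compared with tumor over the 11 region libraries of patient 1. Those p-values describe the spread between regions of 1 patient and are too small a base for a statement about patients. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic, and was not computed for changes under 0.01. Levels of genes fitted in these comparisons are CPM (UMI counts scaled by edgeR to TMM-adjusted library sizes), with the SD over patients or libraries. All other levels, such as those of tumor regions, clusters and multimer-sorted cells, are CPM scaled to the plain UMI total.

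There were 23 gene lists, fixed before the data were examined along with the comparisons, tests and most alternative settings. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of list members are also given adjusted over the list alone. The genes named were the 5 largest rises and 5 largest falls among called genes with a mean of at least 20 CPM that moved in the same direction in every patient (for adrenal tumor, without overlap of the libraries). For each list they were up to 3 called members with the largest change or, where none was called, the member with the smallest p. CD8A, CD8B, CD4, CD3D and CD3E served as a check of the gates. In the multimer-sorted cells the 3 members of a list with the highest median CPM were taken. One gene named by this rule is not reported here.

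Correlations over tumor regions used the mean log2(CPM + 1) of a list per region. They were computed over the 24 regions centred per patient with 100000 permutations within patients, and within each patient with an exact permutation test over 8 regions. Benjamini-Hochberg adjustment covered the 4 pooled and the 12 within-patient tests separately. Multimer-sorted cells were described by levels only.

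The tests were tried on simulated counts with 67 genes each at 1.5 and 2-fold and 66 at 4-fold. At 4-fold they called 95.5% of the genes in the CD8 comparison of tumor with normal, 86.4% in the CD4 comparison, 75.8% in the CD8 comparison of lymph node with tumor, 86.4% in the CD4 one and 75.8% in the interaction. At 2-fold the corresponding shares were 50.7%, 32.8%, 28.4%, 22.4% and 23.9%, and at 1.5-fold at most 2.99%. Over the region libraries of patient 1 they called 89.4% (CD8) and 86.4% (CD4) at 4-fold. Of the genes simulated without a change, 0.017 to 0.179% were called. Each gene was simulated independently of the others at its fitted dispersion, whereas genes of a list can vary together in the data. In the data ENTPD1 changed over 4-fold in the CD8 comparison of tumor with normal and was not called. A count of 0 therefore does not mean that no gene changed 4-fold.

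Alternatives were DESeq2 1.42.0 size factors or its Wald test, no filter on low counts, at least 2 gate UMIs, a stricter cell filter (500 genes, 5% mitochondrial UMIs), doublet removal, regions weighted equally, region libraries as units, only the tissues compared, no replicate block and leaving out each replicate. For shares, the clustering resolution and centring were varied, and for correlations the pseudocount, the scaling and a filter on low genes. Scrublet in scanpy 1.11.5, at its own threshold, marked at most 0.192% of the cells of a library. Removal of the highest scores at 0.8% per 1000 barcodes was therefore added after the data had been examined. Runs without 3 tumor libraries in doubt and, for the shares, without each patient were added at the same stage. The 4 feature-barcode samples of the multimer-sorted cells had no files and were not analysed.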

Results

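The data are single-cell transcriptomes of CD3+ T cells in 32 libraries from 3 patients who had lung cancer and received an antibody that blocks the inhibitory receptor PD-1. There were 24 tumor libraries (8 regions in each patient), 3 of adjacent normal tissue, 2 of lymph node (patients 1 and 2) and 3 of adrenal tumor (patient 1). Total UMIs per library ranged from 10845951 to 34631369. After filtering, 192018 cells remained, of which 71277 entered the CD8 gate and 34122 the CD4 gate. A separate set of 16 files held multimer-sorted CD8 T cells of patient 1, with 143 to 11304 cells and 331695 to 47135547 UMIs each. One tumor library stood apart in depth, since region 1 of patient 3 had a median of 1071 UMIs per cell, against 2604 to 3298 in the other regions of that patient. Another pair, tumor regions 7 and 8 of patient 1, differed from regions 1 to 6 of the same tumor by over 2-fold without overlap, with 86 genes higher and 598 lower in the CD8 gate. By the same rule no other pair of these 8 regions parted from the rest at more than 7 genes.

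The first comparison asked how CD8 T cells in tumor differed from those in adjacent normal tissue of the same patients. CD8-gated cells of tumor held more RNA of the list of exhaustion and tumor reactivity genes, which mark T cells under chronic stimulation. Of its 16 members 15 had a positive log2 fold change, and the mean over the list was 1.2 (camera adjusted p 1.76e-37, adjusted p = 0.121 with an estimated correlation). ENTPD1 (ENSG00000138185), which encodes the ectonucleotidase CD39, stood at 44.4 ± 9.34 CPM in tumor and 10.2 ± 3.23 CPM in normal tissue (SD, n = 3 patients; log2 fold change 2.17 ± 0.25 SE). It was higher in 3 of 3 patients, with an edgeR adjusted p of 0.120. ITGAE, the integrin chain CD103 of tissue-resident cells, was at 149 ± 68.3 and 78.9 ± 32.9 CPM (log2 fold change 0.90 ± 0.17 SE, higher in 3 of 3 patients). S1PR5, a receptor of circulating cytotoxic cells, was at 11.6 ± 11.6 CPM in tumor and 38.6 ± 40.7 CPM in normal tissue, lower in 3 of 3 patients (log2 fold change -1.69 ± 0.21 SE).

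By edgeR, 0 of 11966 genes passed the threshold in the CD8 comparison of tumor with normal tissue, 670 had an unadjusted p under 0.05, and the DESeq2 Wald test called 57. Adjusted over the list alone, 12 of the 16 exhaustion genes passed, all higher in tumor, and none of them passed over all genes. The count was 388 without patient 1, 187 without patient 2 and 0 without patient 3.

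Among the other lists in CD8-gated cells, all 15 interferon response genes had positive fold changes (mean 1.02, camera adjusted p 7.08e-11, adjusted p = 0.386 with an estimated correlation). Tumor region 1 of patient 3 stood above the other regions of its patient for this list, and without it the adjusted p were 4.05e-11 and, with an estimated correlation, 0.38. The interferon gene IFIT1 was at 15.2 ± 23.2 CPM in tumor and 1.69 ± 1.12 CPM in normal tissue. All 15 proliferation genes were positive too (mean 0.46, adjusted p 2.55e-08, adjusted p = 0.331 with an estimated correlation), with adjusted p of 2.44e-06 and, with an estimated correlation, 0.38 without tumor region 1 of patient 3, which was again the highest region of its patient. UBE2C, a ubiquitin carrier of mitosis, was at 16.5 ± 8.37 and 8.58 ± 4.28 CPM. The lists of regulatory T cell (9.6e-07), follicular helper (4.37e-05), type 17 (0.00143) and tissue residency genes (0.00195) also ranked higher in tumor by camera adjusted p. With an estimated correlation their adjusted p were 0.331, 0.331, 0.331 and 0.405. Cytotoxic effector (adjusted p 0.0019), MAIT (0.0253) and metallothionein genes (0.00184) ranked lower, at 0.423, 0.557 and 0.405 with an estimated correlation. For the exhaustion, interferon and proliferation groups alike, B and plasma cell genes (mean 2.03, adjusted p 0.00184) and heat shock genes (mean 0.73, adjusted p 0.00352) moved in the same direction as the group, at adjusted p = 0.331 and 0.642 with an estimated correlation. Of 9 B and plasma cell genes 2 were negative, and MS4A1, the member with the smallest p, was at 5.57 ± 5.64 CPM in tumor and 9.94 ± 10.45 CPM in normal tissue, lower in 3 of 3 patients. HSPA1A, a stress-induced chaperone, was at 325 ± 119 CPM in tumor and 58.0 ± 43.0 CPM in normal tissue.

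The other 10 lists measured in this comparison did not pass in camera, with adjusted p from 0.132 to 1. They were the naive, GZMK effector memory, gamma-delta and NK, glucocorticoid, hypoxia, steroidogenic, lung epithelium, myeloid, fibroblast and endothelium, and red cell lists. For lung epithelium the median of 0.128 and the test were positive and the mean of -0.31 negative. The gate genes differed little: CD8A was at 996 ± 255 CPM in tumor and 1031 ± 136 CPM in normal tissue, and CD3E at 1294 ± 274 and 1250 ± 158 CPM.

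The second comparison asked the same of CD4 T cells. In CD4-gated cells all 12 regulatory T cell genes had positive fold changes in tumor (mean 0.91), and IKZF2 (ENSG00000030419), which encodes the transcription factor Helios, was at 44.7 ± 42.6 CPM in tumor and 17.6 ± 13.7 CPM in normal tissue (SD, n = 3 patients). Its log2 fold change of 1.2 ± 0.18 SE was positive in 3 of 3 patients. Of 15 exhaustion genes 14 were positive (mean 1.2), among them the costimulatory receptor gene TNFRSF9 at 42.1 ± 21.6 and 23.8 ± 11.5 CPM. TNFSF13B, which encodes the B cell survival factor BAFF, had the smallest p of the type 17 list, at 29.0 ± 12.2 and 8.50 ± 3.66 CPM, higher in 3 of 3 patients. The cytotoxic list had 11 of 15 genes negative, and S1PR5 was at 2.56 ± 3.60 and 7.28 ± 8.81 CPM.

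By edgeR, 0 of 10843 genes passed in the CD4 comparison of tumor with normal tissue (adjusted p 0.497 for IKZF2 and TNFRSF9 and 0.287 for TNFSF13B), 752 had an unadjusted p under 0.05, and the DESeq2 Wald test called 23. Adjusted over the list alone, 5 of 12 regulatory T cell genes and 9 of 15 exhaustion genes passed. In camera the exhaustion (adjusted p 8.86e-18), regulatory T cell (6.03e-15), follicular helper (1.16e-07) and interferon lists (0.00103) ranked higher in tumor. With an estimated correlation their adjusted p were 0.305, 0.28, 0.305 and 0.668. The cytotoxic (4.93e-05), MAIT (1.54e-06), tissue residency (0.0234) and metallothionein lists (0.00349) ranked lower, at 0.305, 0.348, 0.571 and 0.61 with an estimated correlation. Beside the regulatory T cell and exhaustion groups, B and plasma cell genes were higher in the CD4 gate of tumor. CD79A, a B cell receptor component, was at 17.4 ± 13.1 CPM in tumor and 2.15 ± 1.82 CPM in normal tissue, and the list had an adjusted p of 2.41e-12 (adjusted p = 0.28 with an estimated correlation). Heat shock genes moved with them (adjusted p 0.00248, and 0.718 with an estimated correlation), and HSPA6 was at 7.003 ± 5.53 and 0.179 ± 0.310 CPM. The other 12 lists had adjusted p from 0.21 to 0.939, and the median, mean and test differed in sign for the naive, type 17, myeloid and red cell lists. The count of 0 was 751 without patient 1, 59 without patient 2 and 0 without patient 3.

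Whether CD8 and CD4 T cells differed in their response was tested as an interaction. By edgeR, 0 of 13087 genes passed, 321 had an unadjusted p under 0.05, and the DESeq2 Wald test called 1. The CD8 minus CD4 difference was positive for 15 of 15 genes of the proliferation list, with a mean of 0.52 (camera adjusted p 9.98e-10, adjusted p = 0.531 with an estimated correlation). In the CD4 gate alone this list had 5 positive and 10 negative genes (camera adjusted p 0.366). For UBE2C the difference was 1.06 ± 0.36 SE on the log2 scale, positive in 3 of 3 patients. Tissue residency genes were positive for 9 of 11 members (mean 0.64, adjusted p 7.07e-09, adjusted p = 0.129 with an estimated correlation), and ZNF683, a transcription factor of tissue-resident cells, differed by 1.12 ± 0.24 SE in 3 of 3 patients. Regulatory T cell genes were negative for 9 of 12 members (mean -0.26, adjusted p 0.0112, adjusted p = 0.531 with an estimated correlation). For B and plasma cell genes the difference was negative (mean -1.35, adjusted p 2.88e-05, adjusted p = 0.129 with an estimated correlation). Cytotoxic (0.00123), MAIT (0.00447) and type 17 lists (0.00856) also passed, each at adjusted p = 0.531 with an estimated correlation. The other 16 lists, among them mast cells with 1 measured gene, had adjusted p from 0.0689 to 0.994. The signs of median, mean and test differed for the gamma-delta and NK, heat shock, hypoxia, lung epithelium, myeloid and red cell lists.

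Shares of cell classes were compared in the same tissues. Regulatory T-like cells made up 11.01 ± 10.96% of CD3-sorted cells in tumor and 4.46 ± 2.18% in normal tissue (SD, n = 3 patients) and were higher in 3 of 3 patients. CD4 follicular helper-like cells were at 4.599 ± 7.618% and 0.347 ± 0.568%, also higher in 3 of 3. The rise lay mostly in patient 3 (13.3933% and 1.0021%). Patient 1 had only 0.0256% and 0.0%, and patient 2 only 0.3786% and 0.0393%. CD8 cytotoxic effector-like cells were at 3.36 ± 5.70% in tumor and 10.6 ± 14.9% in normal tissue, lower in 3 of 3. The fall lay in patients 1 (9.948% and 27.645%) and 2 (0.117% and 4.0102%). Patient 3 had 0.0247% and 0.0795%, the latter only 5 cells. For each of these 3 classes the exact two-sided sign-flip p was 0.25, the smallest that 3 patients allow. Tissue resident-like cells were at 13.4 ± 12.2% and 11.3 ± 10.0% and GZMK memory-like cells at 15.4 ± 10.7% and 15.1 ± 8.04%, differences within the spread between patients. A mean of 37.5% of the cells of a tumor library (16.66 to 92.99%) and 37.6% of a normal library (23.06 to 59.03%) lay in clusters without a class name. Of these, cluster 2 held 26.4% of tumor and 52.9% of normal cells in patient 3. Cluster 9, with GNG4 and CXCR5 among its top genes, held 27.4% of tumor and 2.42% of normal cells in patient 2. Such imbalance within a patient limits what these class shares can show.

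**Figure D1:**
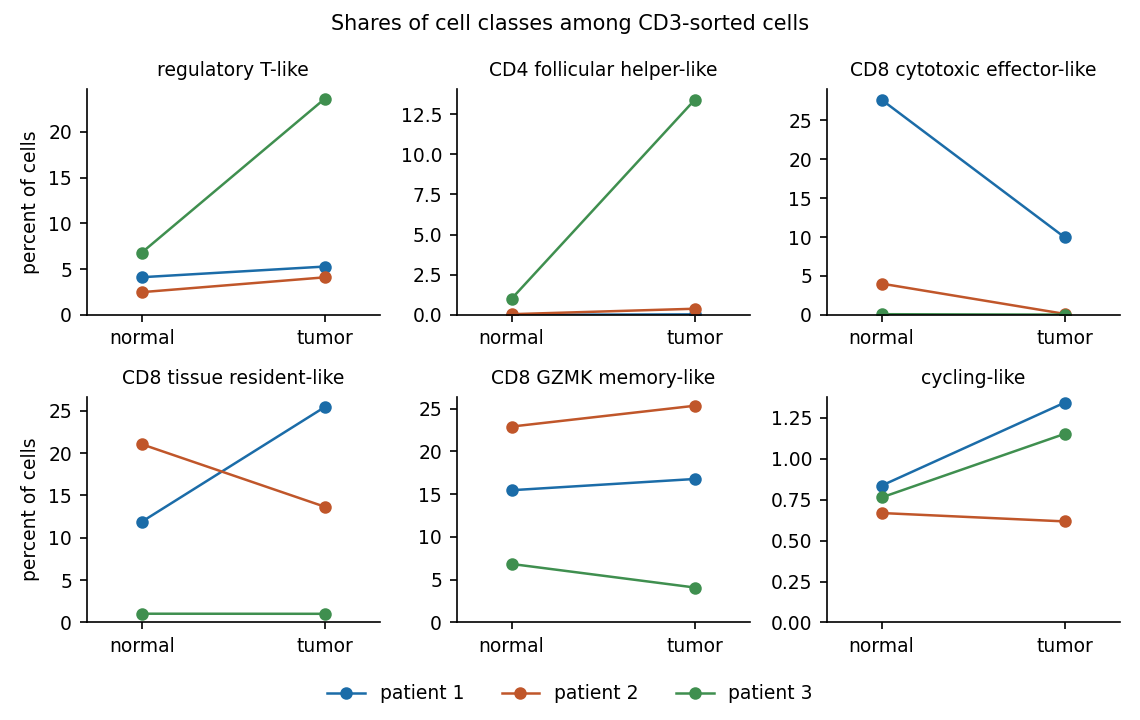
Shares of 6 cell classes among CD3-sorted cells (y axes, percent of cells) in adjacent normal tissue and tumor (x axes), with 1 line per patient and tumor values averaged over 8 regions. Regulatory T-like cells were higher and cytotoxic effector-like cells lower in tumor in each patient, and the sizes differed widely between patients. Cytotoxic effector-like cells of patient 3 were at only 0.0247% in tumor and 0.0795% in normal tissue.

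The lymph node comparison asked how T cells of lymph node differed from those of tumor in the 2 patients with both. In CD8-gated cells, 5 of 12 members of the naive, central memory and progenitor list rose in lymph node, and all 12 had positive fold changes. LEF1 (ENSG00000138795), a transcription factor of naive T cells, was at 80.2 and 123 CPM in the lymph nodes of patients 1 and 2 and at 12.3 and 26.6 CPM in their tumors (log2 fold change 2.35 ± 0.28 SE, edgeR adjusted p 0.0247). ACTN1, an actin crosslinker, rose by 3.23 ± 0.39 SE (adjusted p 0.0247). Outside the lists, CHI3L2 rose by 2.61 ± 0.40 SE and the kinase gene TXK by 2.59 ± 0.35 SE (adjusted p 0.0356 and 0.0279), and MAL of the naive list by 2.49 ± 0.36 SE (0.0342).

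Of 11 tissue residency genes 5 fell in lymph node, including ZNF683, identifier ENSG00000176083 (log2 fold change -2.61 ± 0.22 SE, adjusted p 0.0131), the integrin gene ITGA1 (-1.94 ± 0.32 SE, 0.0451) and CAPG (-1.80 ± 0.28 SE, 0.0375). GZMB (ENSG00000100453), the cytolytic protease granzyme B, was at 305 and 23.4 CPM in lymph node and at 1265 and 587 CPM in tumor (-3.35 ± 0.55 SE, 0.0424), and 14 of 15 cytotoxic genes did not pass. KRT86 (-5.24 ± 0.82 SE, 0.0356) and the inhibitory receptor gene HAVCR2 (-1.28 ± 0.23 SE, 0.0490) fell among 16 exhaustion genes. METRNL, KLRC1, LDLRAD4 and ANKRD28 completed the largest falls among called genes with a mean of at least 20 CPM, from -3.20 to -2.72 on the log2 scale. KLRC1, an NK cell receptor, was the only called gene of the gamma-delta and NK list, as was CCR6 (-2.13 ± 0.37 SE, 0.0464) of the type 17 list and CD200 of the follicular helper list, which rose by 1.43 ± 0.25 SE (0.0465).

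**Figure D2:**
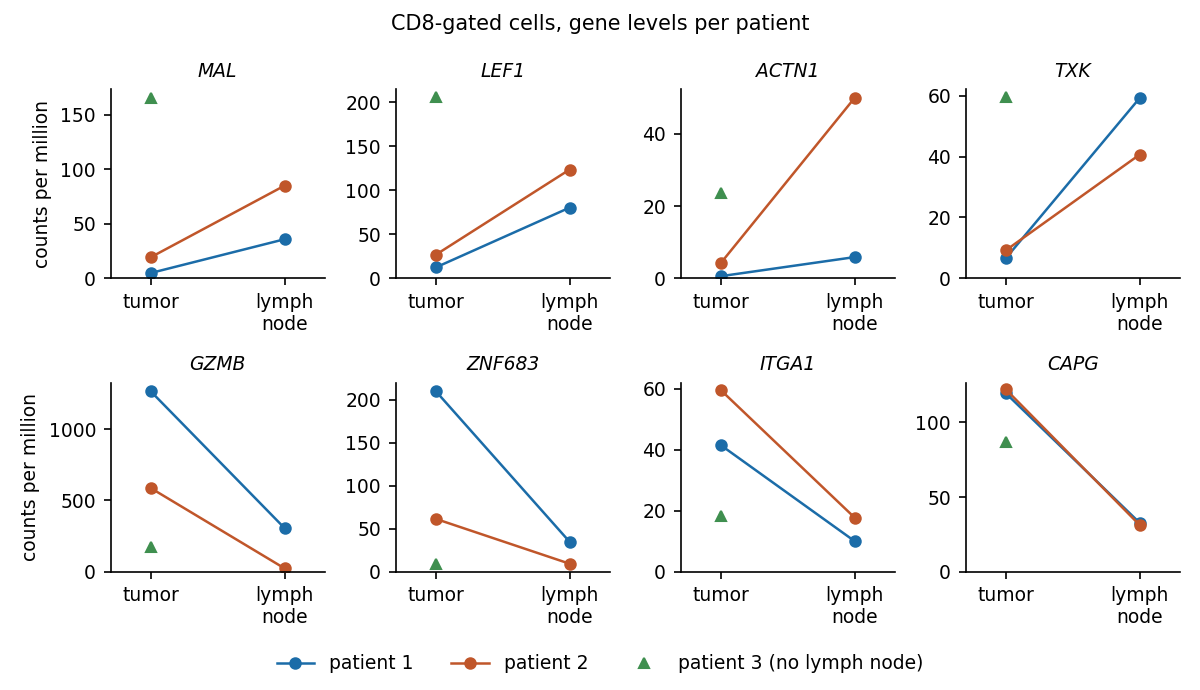
Levels of 8 named genes in CD8-gated cells (y axes, CPM from 0) in tumor and lymph node (x axes), as 1 line for each of patients 1 and 2 and a triangle for the tumor of patient 3, which has no lymph node library. MAL, LEF1, ACTN1 and TXK were higher and GZMB, ZNF683, ITGA1 and CAPG lower in lymph node in both patients.

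In all, edgeR called 116 of 11966 genes in the CD8 comparison of lymph node with tumor, 60 higher and 56 lower in lymph node, each in the same direction in both patients. B cell genes moved with the naive group, since CD79A rose from 0.921 to 2.84 CPM in patient 1 and from 4.83 to 34.1 CPM in patient 2 (2.36 ± 0.32 SE, adjusted p 0.0281). HSPA6 was at 559 and 27.1 CPM in lymph node and 32.3 and 16.6 CPM in tumor without passing (adjusted p 0.176). With no replicate block, that is without the patient in the model, 0 genes passed. Without patient 3, who has no lymph node library and enters the spread through tumor and normal tissue, 0 passed as well, while 2007 passed without patient 1 and 614 without patient 2. MAL was at -0.08 on the log2 scale with no replicate block, against the rise of 2.49 within patients.

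In camera the CD8 naive list ranked higher in lymph node (adjusted p 7.53e-15) and the tissue residency (4.91e-15), exhaustion (3.57e-08), type 17 (4.6e-08), cytotoxic (9.87e-07) and proliferation lists (1.76e-05) ranked lower. With an estimated correlation the adjusted p were 0.22 for the first 4 of these lists, 0.279 for cytotoxic and 0.298 for proliferation genes. The hypoxia (0.000291), glucocorticoid (0.00353) and gamma-delta and NK lists (0.0113) ranked lower and the B and plasma cell list higher (0.00511), at 0.279, 0.565, 0.264 and 0.266 with an estimated correlation. The median of the B and plasma cell list was -0.02, opposite in sign to its mean of 0.44 and its test. Adjusted over the list alone, 8 naive genes rose and 9 tissue residency, 10 cytotoxic, 10 type 17 and 7 exhaustion genes fell. The other 12 lists had adjusted p from 0.0806 to 0.87.

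In CD4-gated cells ZNF683 was at 0.784 ± 1.11 CPM in lymph node (SD, n = 2) and 8.52 ± 13.9 CPM in tumor (n = 3), with a log2 fold change of -3.98 ± 0.41 SE, lower in 2 of 2 patients. GZMH, another granzyme, was at 24 ± 15.1 and 97.0 ± 131 CPM (-2.31 ± 0.30 SE), and the chemokine gene CCL4 at 161 ± 177 (160.5) and 864 ± 1080 CPM (-3.49 ± 0.51 SE), each lower in 2 of 2 patients. ACTN1 of the naive list was at 39.9 ± 26.1 and 13.1 ± 9.65 CPM. By edgeR, 0 of 10843 genes passed in the CD4 comparison of lymph node with tumor (adjusted p 0.0552 for ZNF683), 1625 had an unadjusted p under 0.05, and the DESeq2 Wald test called 214. Adjusted over the list alone, 7 cytotoxic, 6 tissue residency and 4 GZMK genes were lower and 5 naive genes higher.

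By camera the CD4 cytotoxic (adjusted p 1.9e-09), GZMK (1.42e-08), tissue residency (1.42e-08) and type 17 lists (5.26e-07) ranked lower in lymph node, at 0.189, 0.189, 0.189 and 0.332 with an estimated correlation. The hypoxia (0.000103), glucocorticoid (0.000156), exhaustion (0.00139) and gamma-delta and NK lists (0.019) also ranked lower, at 0.387, 0.531, 0.539 and 0.327. The naive (0.000334) and fibroblast and endothelium lists (0.00151, 2 genes) ranked higher, at 0.539 and 0.273. The other 12 lists had adjusted p from 0.0762 to 0.986, with signs that differed for the follicular helper, metallothionein, myeloid and B and plasma cell lists. HSPA6 stood at 143 ± 181 CPM in lymph node and 7.003 ± 5.53 CPM in tumor, beside the naive group. The count of 0 was 14 with at least 2 gate UMIs and 24 with the stricter cell filter, 1345 without patient 1, 199 without patient 2 and 0 without patient 3. Tissue resident-like cells made up 0.739 ± 0.975% of lymph node and 19.6 ± 8.33% of tumor cells (n = 2), lower in 2 of 2 patients, with an exact sign-flip p of 0.5, the smallest possible. In lymph node 65.0% of cells had no class name. Cluster 17, which took 88.2% of its cells from 1 library, held 80.9% of lymph node cells of patient 2. Cluster 16, led by heat shock genes, held 37.6% of those of patient 1. Both clusters had no class name, which limits what the class shares of lymph node can show.

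The adrenal tumor of patient 1 was compared with the lung tumor regions of the same patient. CD8 T cells in adrenal tumor carried more RNA of dividing cells: all 15 proliferation genes rose, with a mean log2 fold change of 2.21. TYMS (ENSG00000176890), which makes thymidylate for DNA synthesis, was at 229 ± 77.5 CPM in adrenal tumor (SD, n = 3 regions) and 29.6 ± 20.5 CPM in tumor (n = 8), with a log2 fold change of 2.94 ± 0.60 SE and an edgeR adjusted p of 0.00671. UBE2C rose by 2.84 ± 0.45 SE (0.00239) and the cyclin gene CCNA2 by 2.60 ± 0.39 SE (0.00165). Of 15 interferon response genes 13 rose, with IFI44L at 32.38 ± 16.99 and 2.98 ± 2.30 CPM (3.39 ± 0.49 SE, 0.00146), IFIT1 by 3.14 ± 0.59 SE and RSAD2 by 3.06 ± 0.56 SE. Of 16 exhaustion genes 7 rose, among them GEM by 3.06 ± 0.60 SE (0.00555), TOX2, a transcription factor of exhausted and follicular helper cells, by 2.03 ± 0.46 SE (0.0109) and LAYN by 1.99 ± 0.44 SE (0.00988).

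In these CD8-gated cells, the largest rises and falls were ranked among called genes with a mean of at least 20 CPM and no overlap of the libraries. The largest rises were the chaperone genes HSPA6 (4.38 ± 1.11 SE, adjusted p 0.0196), HSPA1B (3.496 ± 0.82 SE, 0.0135) and HSPA1A (3.15 ± 0.96 SE, 0.0397), together with HMOX1, a heme-degrading stress enzyme (4.32 ± 0.85 SE, 0.00566), and the transcriptional regulator ID3 (3.18 ± 0.47 SE, 0.00154). Thus heat shock genes, 7 of 16 of which rose, moved with the proliferation, interferon and exhaustion groups: HSPA1A was at 3111 ± 941 CPM in adrenal tumor and 350 ± 492 CPM (349.6) in tumor. All 5 measured metallothionein genes, which bind metal ions, rose, with MT1E at 268 ± 154 and 73.3 ± 25.9 CPM (1.87 ± 0.33 SE, 0.00344). In the follicular helper list CD200 rose by 3.62 ± 0.40 SE and BTLA by 1.84 ± 0.25 SE while CXCR5 fell by 2.14 on the log2 scale. The largest falls were RMRP, the RNA of a mitochondrial RNA processing complex (-3.12 ± 0.51 SE, 0.0027), GIMAP1, SELENOM, MT-ATP8 and the cytotoxic cell gene SPON2 (-1.66 ± 0.48 SE, 0.033). GIMAP1 (-1.89 ± 0.58 SE, 0.0404) is among the genes that set tumor regions 7 and 8 of this patient apart. GZMH of the cytotoxic list fell by 0.81 and GZMA rose by 0.58 on the log2 scale. Of the 10 steroidogenic genes of adrenal cortex only FDX1 passed the filter on low counts, at 68.5 ± 4.66 and 50.5 ± 29.1 CPM without passing the test (adjusted p 0.714), and it is among the genes that set tumor regions 7 and 8 apart. The other 9 were at no more than 0.0919 CPM in the CD8 gate and 0.599 CPM in the CD4 gate of any adrenal library, so the gated cells held next to no RNA of these genes.

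**Figure D3:**
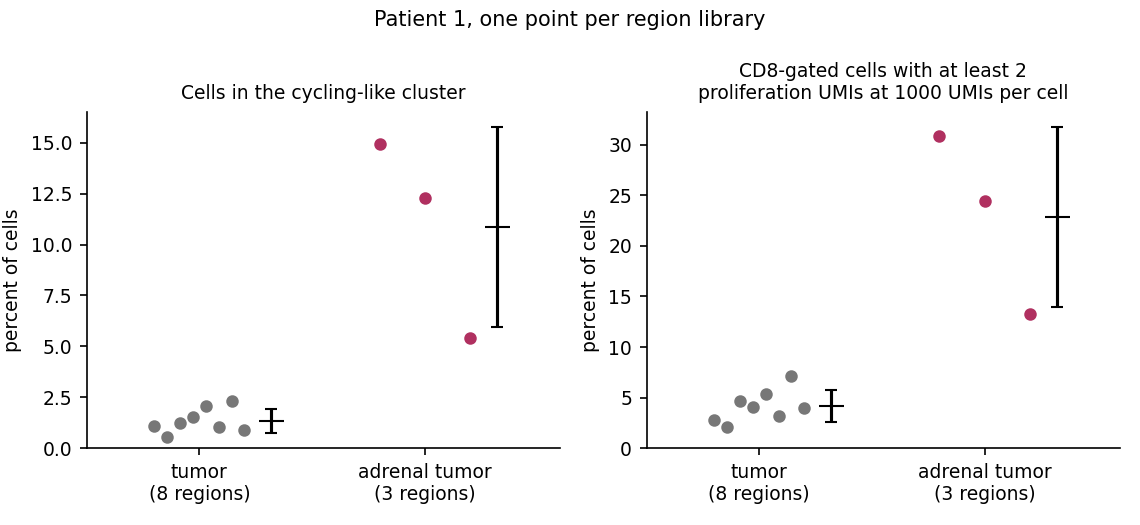
Percent of cells in the cycling-like cluster (left y axis) and percent of CD8-gated cells with at least 2 proliferation UMIs after thinning to 1000 UMIs per cell (right y axis) in the 8 tumor and 3 adrenal tumor region libraries of patient 1 (x axes). Points are libraries and bars the mean ± SD, and each adrenal library lay above the highest tumor library in both.

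Over the regions of patient 1, edgeR called 2171 of 11953 genes in CD8-gated cells, 1421 higher and 750 lower in adrenal tumor. The test describes the spread between regions of 1 patient, and its p is too small a base for a statement about patients. Without tumor regions 7 and 8 the count was 4210, and 908, 869 and 2864 passed when adrenal library 1, 2 or 3 was left out. In camera proliferation (adjusted p 4.44e-19), interferon (3.25e-14), exhaustion (4.44e-05), metallothionein (0.000722), follicular helper and heat shock lists (0.0469 each) ranked higher and glucocorticoid genes lower (0.0197). With an estimated correlation the adjusted p were 0.25, 0.25, 0.326, 0.326, 0.326, 0.557 and 0.555. The other 15 lists had adjusted p from 0.0593 to 0.703. The gate genes CD3E and CD3D fell by 0.51 and 0.37 on the log2 scale (adjusted p 0.026 and 0.0488).

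In CD4-gated cells of the adrenal tumor 13 of 15 proliferation genes rose, with TOP2A (ENSG00000131747), a topoisomerase of dividing cells, at 88.0 ± 39.5 CPM in adrenal tumor and 18.2 ± 7.35 CPM in tumor (log2 fold change 2.28 ± 0.31 SE, adjusted p 0.00237). TYMS rose by 2.32 ± 0.62 SE and UBE2C by 2.04 ± 0.34 SE. Of 13 interferon genes 9 rose, including RSAD2 (3.56 ± 0.68 SE, 0.01), OAS1 (2.27 ± 0.40 SE, 0.00655) and IFI6 (2.17 ± 0.33 SE, 0.00331). The follicular helper genes CD200, IL21 and BTLA rose, IL21 from 8.997 ± 4.005 to 45.5 ± 13.6 CPM (2.28 ± 0.32 SE, 0.00262), and of 16 exhaustion genes HAVCR2 (1.25 ± 0.26 SE) and GEM (1.38 ± 0.37 SE) rose. HSPA6 (5.15 ± 0.92 SE, 0.00733), the collagen chaperone gene SERPINH1 (3.52 ± 0.66 SE, 0.00974), TSPAN13 (3.36 ± 0.54 SE, 0.00483), HSPA1B (3.35 ± 0.68 SE, 0.0137) and CD38 (2.55 ± 0.43 SE, 0.00597), an activation marker, were the largest rises, so heat shock genes (6 of 16 rose) moved with the other groups. RMRP (-3.05 ± 0.41 SE, 0.00237), GZMB (-1.59 ± 0.34 SE, 0.0174), PASK, PLEC and JAML fell most. These largest rises and falls were ranked among called genes with a mean of at least 20 CPM and no overlap of the libraries.

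In CD4-gated cells of patient 1, edgeR called 723 of 9971 genes, of which 197 were lower in adrenal tumor and the others higher. This p too is over regions of 1 patient and too small a base for a statement about patients. The count was 1797 without tumor regions 7 and 8, 193 with at least 2 gate UMIs, 143, 261 and 1242 without adrenal library 1, 2 and 3. Without tumor region 1, 2, 3 or 6 it was 447, 432, 420 or 425. By camera the proliferation list ranked higher (adjusted p 5.78e-24, adjusted p = 0.0498 with an estimated correlation, and 0.121 in that test without tumor regions 7 and 8), as did the interferon (6.42e-09), exhaustion (0.000259), follicular helper (0.00251), heat shock (0.00919), metallothionein (0.00919) and gamma-delta and NK lists (0.0124). Glucocorticoid genes ranked lower (0.0155). With an estimated correlation these 7 had adjusted p of 0.314, 0.332, 0.118, 0.422, 0.422, 0.118 and 0.447. The other 13 lists had adjusted p from 0.0615 to 0.689. Among cell classes, cycling-like cells made up 10.9 ± 4.90% of the 3 adrenal libraries and 1.34 ± 0.60% of the 8 tumor libraries of the patient. Tissue resident-like cells were at 8.71% and 25.4%, and 59.3% of adrenal cells had no class name. Cluster 8, without a class name and led by CCL3, HSPA6 and HMOX1, held 40.6% of adrenal and 1.40% of tumor cells of the patient. It took 50.9% of its cells from 1 library. Its CD8A level was 1008.5 CPM, so the named CD8 classes leave out many CD8 cells of adrenal tumor. The lower tissue resident-like share cannot be read as a loss of such cells.

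Across the 24 tumor regions, centred per patient, the level of exhaustion genes in CD8-gated cells was compared with 4 other levels. It rose with interferon response genes in the same cells (Pearson r 0.687, permutation p 0.00025, adjusted p 0.0005; Spearman rho 0.659, permutation p 0.00125), and r was 0.712 without the 2 regions farthest from the median. With regulatory T cell genes in CD4-gated cells r was 0.648 (permutation p 0.00091, adjusted p 0.00121; rho 0.651, permutation p 0.00156), and 0.534 without the 2 farthest. With proliferation genes in CD8-gated cells r was 0.858 (permutation p 4e-05, adjusted p 0.00016; rho 0.540, permutation p 0.0114), and 0.835 without the 2 farthest. With naive and progenitor genes r was -0.365 (permutation p 0.111; rho -0.302, permutation p 0.178) and did not pass.

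Within single patients, each with 8 regions and an exact permutation test, 3 of 12 relations passed the adjusted threshold by Pearson r and none by Spearman rho. In patient 1 they were regulatory T cell genes (r 0.882, exact p 0.00325, adjusted p 0.0195; rho 0.810, exact p 0.0218, adjusted p 0.0871) and proliferation (r 0.937, exact p 0.000893, adjusted p 0.0107; rho 0.857, exact p 0.0107, adjusted p 0.0643). In patient 2 it was the interferon response (r 0.858, exact p 0.00801, adjusted p 0.032; rho 0.857, exact p 0.0107, adjusted p 0.0643). The relation with proliferation rested on 2 regions in patients 2 and 3, since r went from 0.915 to -0.631 and from 0.793 to -0.079 without the 2 farthest. That with interferon genes fell to 0.305, 0.429 and 0.0541 in patients 1, 2 and 3 on the same removal. For regulatory T cell genes r became 0.734, 0.199 and 0.912, from 0.882, 0.610 and 0.169. Without regions 7 and 8 of patient 1, the 6 regions left gave r of 0.859 with regulatory T cell genes (exact p 0.0389) and 0.921 with proliferation (exact p 0.0431), and rho of 0.657 with an exact p of 0.175 for both.

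**Figure D4:**
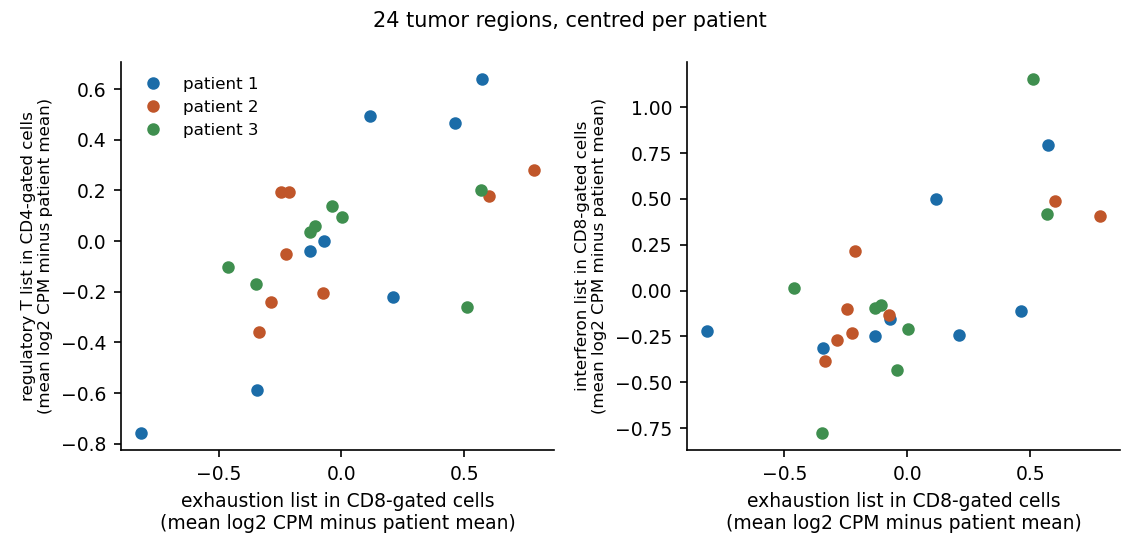
Mean log2 CPM of the regulatory T cell list in CD4-gated cells (left y axis) and of the interferon list in CD8-gated cells (right y axis) against the exhaustion list in CD8-gated cells (x axes) in 24 tumor regions, each value minus its patient's mean, colored by patient. Pearson r was 0.648 and 0.687.

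The multimer-sorted CD8 T cells of patient 1 were described across tissues without a test, as median CPM over region files with the lowest and highest file. Of the 12 naive and memory genes the 3 most abundant had their highest median in lymph node, and the files overlapped with those of tumor for KLF2 and NELL2. IL7R, the receptor of a T cell survival cytokine, was at 1418 (1052 to 1542) CPM in 4 lymph node files, 585 (259 to 724) in 8 tumor files and 67.0 (28.6 to 468) in 4 adrenal files. The 3 most abundant of 15 cytotoxic and of 12 GZMK effector memory genes had their lowest median there, with GZMB at 428 (163 to 473), 1659 (1237 to 3147) and 1524 (1323 to 2212) CPM and CCL4 at 781 (428 to 881), 7524 (2495 to 11945) and 7513 (6236 to 8988) CPM in the same order. The 3 most abundant proliferation and interferon genes, of 15 each, had their highest median in adrenal files, and their files overlapped with those of tumor. STMN1, a regulator of dividing cells, was at 482 (346 to 659) against 206 (141 to 459) CPM in tumor, and IFI6 at 257 (121 to 334) against 51.9 (21.1 to 134) CPM. The inhibitory receptor gene LAG3 was at 561 (407 to 671), 232 (185 to 468) and 205 (140 to 211) CPM in adrenal, tumor and lymph node files. The other abundant exhaustion genes differed less between adrenal and tumor files. CTLA4 was at 272 (149 to 479) and 251 (120 to 434) CPM, and PHLDA1 at 356 (247 to 421) and 271 (170 to 404) CPM. For all 3 genes the adrenal and tumor files overlapped. The smallest of these files held 42 gated cells, and the lymph node and adrenal files came from 1 sorted pool each. The tumor files came from 2 pools, with regions 7 and 8 in a pool of their own.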

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

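All tests of explanations in this part were set with their predictions before their outcome was seen, on patterns first noticed in the same data, and the one in cells of 1000 to 2000 UMIs was added after the stricter filter had been tried. The search for libraries far from the others of their group made 57 tests over the 8 tumor regions of a patient and marked 9, while chance marks about 1 in 20 groups. Of the 9, 6 fell on a single library.

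That library was tumor region 1 of patient 3, which lay far from the other 7 regions of the patient in 6 measures. Its median was 1071 UMIs per cell (others 2604 to 3298), and 84.92% of its cells had a CD3 UMI (others 96.36 to 98.78%). It held 1.934% regulatory T-like cells (others 25.25 to 29.44%), 0.4251% CD4 follicular helper-like cells (12.67 to 18.05%), 1.15% CD8 GZMK memory-like cells (4.104 to 4.823%) and 0.6085% plasma cell-like cells (0.0402 to 0.0871%). In this library 92.99% of cells lay in clusters without a class name, most of them in cluster 7, led by IFIT genes. This limits what its class shares can show. Its regulatory T cell list stood at a mean log2 CPM of 6.499 in CD4-gated cells (others 6.590 to 6.961). In other libraries, tumor region 1 of patient 1 held 25.28% CD8 GZMK memory-like cells (others 13.02 to 18.47%). Tumor region 2 of patient 2 held 0.0896% CD8 exhausted-like cells (0 to 0.0384%), which is only a handful of its 4463 cells. Tumor region 3 of patient 2 held 8.039% plasma cell-like cells (1.757 to 4.106%).

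In the same library the interferon list stood at a mean log2 CPM of 6.991 in CD8-gated cells, above the highest of the other 7 regions (6.258). Shallow or damaged cells were weighed as a source by repeating the measure in cells past the stricter filter. The library then stood at 7.006 and the others at 5.143 to 6.353, but its cells were still the shallowest, so this decides nothing. In cells of 1000 to 2000 UMIs, with 61 cells drawn from each library, it stood at 6.878 and the others at 4.093 to 6.235. The 95% interval of its lead over the highest other was -0.299 to 1.007, so shallow cells stay open as a source. Damaged cells, a difference in library preparation and a state of this tumor region stay open too, since the region has 1 library.

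Tumor regions 7 and 8 of patient 1 differed from regions 1 to 6 by over 2-fold without overlap, with 86 genes higher and 598 lower in the CD8 gate and 67 higher and 594 lower in the CD4 gate. A state of these 2 regions was weighed in the separate multimer-sorted libraries of the same regions, over 563 genes apart in both gates. There the genes had a median signed log2 difference of 0.02988 (95% interval over resampled genes -0.004 to 0.0705) against 1.87 in the CD3-sorted libraries. The interval does not cover the spread between files or pools. The value of 1.87 is raised by the choice of the genes in those same libraries. The multimer-sorted cells of regions 7 and 8 came from a sorted pool of their own, apart from that of regions 1 to 6. The values argue against a state shared by multimer-sorted cells, unless a difference between the pools offset it. A state of other T cells stays open. Low UMI counts of single cells were argued against too, since shallow and deep CD8-gated cells of regions 1 to 6 differed by a median of -0.009699 at these genes. Both kinds of cell came from the same libraries, so the sequencing depth of a library was not varied and stays open. Gene counting with another annotation was weighed through genes absent from one set of libraries and above 20 CPM in the other, which were 0.0% of the 563. The libraries list the same features and the rule needs no UMI in any gated cell, so it speaks only against genes missing entirely. Some genes were far apart by nearly the same amount in both gates without meeting it. MTRNR2L12 had log2 differences of -8.425 (CD8) and -8.44 (CD4), and EEF1G of 5.303 and 5.323. Another annotation stays open where genes are counted in part, as does an unlabelled library or sequencing batch.

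The cycling-like share of adrenal tumor was the third pattern weighed. With the highest doublet scores removed, the lowest adrenal library held 5.461% cycling-like cells and the highest tumor library of patient 1 held 2.431%. That argues against doublets that the scores mark. Cells with UMIs of both CD4 and CD8 made up 2.257 to 3.018% of the adrenal and 1.093 to 1.64% of the tumor libraries of the patient. The cycling-like cluster had a median of 2.449 times its libraries' median UMIs, so doublets without a high score stay open. After thinning each cell to 1000 UMIs, 13.267% of CD8-gated cells of the lowest adrenal library had at least 2 proliferation UMIs, against at most 7.156% in tumor, which argues against depth. The tissue and the library preparation of the adrenal samples cannot be told apart in 1 patient.

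The CD8 and CD4 responses in tumor differed for 7 gene lists in camera on the interaction at the preset correlation, and for none with an estimated correlation (adjusted p = 0.129 to 0.531). The mean CD8 minus CD4 difference on the log2 scale was 0.247 for cytotoxic effector, 0.644 for tissue residency, 0.545 for type 17, 0.52 for proliferation, 0.472 for MAIT, -0.257 for regulatory T cell and -1.35 for B and plasma cell genes. No explanation was tested for these differences.

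UMIs were also present in data that the comparisons did not use, and whether they exceed a background cannot be told. The multimer barcodes of the multimer-sorted files summed to a mean of 345.0 UMIs per cell barcode (median over 16 files, 33.85 to 3015), and no file without multimers was available to set a background.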

How the results depend on the processing

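The runs with the highest doublet scores removed, without tumor regions 7 and 8 of patient 1, without tumor region 1 of patient 3, without these 3 libraries, and without each patient for the shares were chosen after the results had been seen. Across settings, 3405 named-gene values kept their direction and side of the threshold, 238 passed it newly, 271 lost it and 46 reversed. Of the counts, 96 stayed within 1.5 times the reported one and 49 did not. Of the shares, 86 moved by less than the spread between patients and 7 reversed. Of the correlations, 18 kept direction and call. Of the multimer-sorted levels, 133 moved by less than their spread and 5 by more. Where no reason is given below, the cause was not tested.

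The DESeq2 Wald test called 57 genes in the CD8 and 23 in the CD4 comparison of tumor with normal tissue, where edgeR called 0 with 670 and 752 at an unadjusted p under 0.05. It called 518 and 214 in lymph node against tumor, where edgeR called 116 and 0, and 1 in the CD8 minus CD4 difference. Without a filter on low counts the edgeR counts were 343, 127, 1310, 345 and 58 in the same order, with more genes tested. The stricter cell filter gave 4 genes (CD8 tumor against normal), 224 (CD8 lymph node) and 24 (CD4 lymph node). At least 2 gate UMIs gave 14 (CD4 lymph node) and 193 (CD4 adrenal tumor). Region libraries as units gave 14 and 153 in tumor against normal and 1436 and 1044 in lymph node against tumor, with regions of a patient treated as independent. Only the 2 tissues compared gave 62 and 5 in tumor against normal. With no replicate block, 0 genes passed in CD8 lymph node against tumor. Without tumor regions 7 and 8 of patient 1 the adrenal counts were 4210 (CD8) and 1797 (CD4).

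Leaving out 1 patient gave 0 to 388 genes (CD8) and 0 to 751 (CD4) in tumor against normal, and 0 to 2007 (CD8) and 0 to 1345 (CD4) in lymph node against tumor. The 0 came without patient 3 and the highest count without patient 1 each time. Where this left lymph node with 1 sample, the lone sample was assumed to vary like the other groups. Leaving out 1 library gave 869 to 2864 genes (CD8) and 143 to 1242 (CD4) in the adrenal comparison.

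With an estimated inter-gene correlation in camera, the gene lists past the threshold went to 0 in tumor against normal (CD8 0, CD4 0), to 0 and 0 in lymph node against tumor, to 0 in the CD8 minus CD4 difference, to 0 in CD8 adrenal tumor and to 1, proliferation, in CD4 adrenal tumor. The correlation of CD8 exhaustion with naive genes went from -0.365 to -0.4964 with a pseudocount of 10 and to -0.4638 with standardized values, and then passed the threshold. The other 3 correlations kept their call in every setting run.

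Some named genes changed sign. In CD8 tumor against normal these were SGK1 (0.007058, stricter cell filter) and FDX1 (0.01078, without the 3 libraries). In CD4 tumor against normal they were HBB (from 0.8518 to -2.734, DESeq2 Wald test) and CD3E (0.06216 without a filter on low counts, 0.02658 with at least 2 gate UMIs). In CD8 lymph node against tumor CD3D was at -0.04928 without a filter, -0.016 with no replicate block, -0.001268 with region libraries as units and -0.0428 with only the 2 tissues. There CD3E was at 0.02178 with the stricter filter, and MAL, called at 2.493 in the reported fit, at -0.08106 with no replicate block.

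In CD4 lymph node against tumor CD3E was at -0.002115 with DESeq2 size factors, -0.002621 with the DESeq2 Wald test, -0.06905 without a filter, -0.0001627 with at least 2 gate UMIs, -0.06128 with region libraries as units and -0.09138 with only the 2 tissues. CD4 was at -0.03349, -0.07132 and -0.08714 without a filter, with region libraries and with only the 2 tissues. MT2A was at 0.007734 with at least 2 gate UMIs and IKZF2 at -0.09117 with no replicate block. In the CD8 minus CD4 difference HBB was at 2.125 (DESeq2 Wald test) and 0.02617 (at least 2 gate UMIs), MT1F at -0.1126 and CD3E at -0.02799 (both at least 2 gate UMIs) and FDX1 at -0.07653 (stricter cell filter). In CD4 adrenal tumor against tumor CD4 was at 0.001752 without tumor regions 7 and 8.

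Leaving out 1 replicate gave these ranges of log2 fold changes that crossed 0. In CD8 tumor against normal they were -1.63 to 0.4856 for HBA1, -0.1728 to 0.00402 for CD8A and -0.04608 to 0.08588 for CD3E. In CD4 tumor against normal they were -0.08853 to 4.041 for IFIT1, -0.08658 to 0.1129 for CD3E and -0.2034 to 0.09177 for CD4. In CD8 lymph node against tumor they were -0.6143 to 0.01958 for FDX1, -0.2533 to 0.4176 for CD8B and -0.2165 to 0.2118 for CD3D. In CD4 lymph node against tumor they were -0.06102 to 0.09485 for CD3E and -0.05718 to 0.1307 for CD4. In the CD8 minus CD4 difference they were -0.03382 to 0.1514 for CD3E and -0.01495 to 0.1327 for CD3D. In adrenal tumor they were -1.127 to 2.737 for HBB (CD8) and -0.4467 to 2.396 for CD68 (CD4).

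For shares, the tumor minus normal difference of CD8 GZMK memory-like cells was -1.3443 percentage points with double the clustering resolution. Without single patients it ranged from -7.7444 to 0.0056 for naive or central memory-like, -3.7004 to 6.7764 for CD8 tissue resident-like, -0.7203 to 1.8744 for CD8 GZMK memory-like, -0.0102 to 0.735 for CD8 exhausted-like and -0.1313 to 0.2664 for MAIT-like cells.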

Other observations

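The tests over other splits of the samples were set before their results were seen. For 3 tumor against 3 normal profiles there are 10 splits, too few for a share under 0.05. All 10 of 10 gave at least the real count of genes by edgeR in each of the 3 comparisons. With a real count of 0 this was certain in advance, so the share decides nothing. The real counts were 0 (670 genes at an unadjusted p under 0.05, DESeq2 57) in CD8-gated cells, 0 (752, DESeq2 23) in CD4-gated cells and 0 (321, DESeq2 1) in the CD8 minus CD4 difference. The highest other counts were 4, 0 and 1. Splits that, like the real one, put the samples of each patient in different groups gave 0 genes in each comparison (3 such splits beside the real one, edgeR).

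For the adrenal comparison 100 splits of the 11 libraries of patient 1 were drawn, the real one included. In CD8-gated cells 1 of 100 gave as many genes (real 2171, highest other 1346), and in CD4-gated cells 1 of 100 (real 723, highest other 78). Thus no other split drawn reached the real count. Every other split mixed adrenal and tumor libraries within a group, which widens the spread there. The test also cannot tell the tissue from an unlabelled batch of libraries. The highest other split in each gate put tumor regions 7 and 8 together. Without these regions the counts were 4210 and 1797.

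Some clusters drew mostly on a single library and were given no class name. Cluster 7, led by IFIT genes, took 84.3% of its cells from 1 library, tumor region 1 of patient 3. Cluster 17, with TCF7 and GIMAP1 among its top genes, took 88.2% from 1 library, the lymph node of patient 2.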
